A study of Homo sapiens with 9 samples.

How the data were processed

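The material was human CD34+ cells, the blood stem and progenitor fraction, from umbilical cord blood. Cells received the prostaglandin E2 analog 16,16-dimethyl prostaglandin E2 (dmPGE2) or its vehicle for 2 h at 25 °C or 37 °C in a serum-free medium. Per the labels, RNA was isolated with a kit for small samples and turned into biotinylated cRNA after repeated rounds of amplification, then measured on Affymetrix arrays with 54675 probe sets. The deposited values are log2 signals made by RMA in Affymetrix Expression Console, per the submitters' processing notes. RMA corrects background, gives all arrays the same distribution of probe signals and summarises the probes of each set, so a shift shared by most genes cannot be seen in it. The software version, its settings and the arrays that were normalised together are not given in the sources used here. Array medians ran from 6.436 to 6.497 log2 and SDs from 2.291 to 2.378. No pair of arrays held identical values. The number of arrays limits the precision.

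The samples were grouped by the dose and temperature in their labels, which gives 9 arrays in 9 groups of 1. No dose at a given temperature was replicated, and the labels name no donor, pool or batch. Each p-value therefore measures the spread between these arrays of different doses or temperatures, and that spread may be technical. Temperature cannot be told apart from any batch or cell pool that differed between the 4 arrays at 25 °C and the 5 arrays at 37 °C.

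Probe sets were named from the platform annotation, in which 42898 were listed and 11777 were not. Of those listed, 41097 had 1 gene symbol and 1801 had several; the latter were left out. Entrez identifiers matched 41043 probe sets to a current symbol, and 0 symbols changed. A further 59 probe sets for genes tied to sex, and the control probe sets, were left out of every table of genes. For each gene the probe set with the highest mean over the 9 arrays was used, and 10511 genes had more than 1 probe set. Of 19740 genes, 13504 were tested because their signal lay above the array median (the 50th percentile) on at least 2 arrays.

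All tests were run on the deposited log2 values with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment and a threshold of 0.05. The 4 comparisons were fitted separately. The treatment comparison set 5 arrays at 10 µM or more against 2 vehicle arrays with temperature as a covariate, and left 4 residual degrees of freedom. The interaction compared the dmPGE2 effect at 37 °C with that at 25 °C on the same 7 arrays, with 3 residual degrees of freedom. Each vehicle is 1 array, so its own error is not measured in the interaction, where it is assumed to vary like the treated arrays. The temperature comparison used 6 arrays in 3 pairs matched for dose, with 2 residual degrees of freedom. The slope on log10 dose used the 7 treated arrays with temperature as a covariate. Each dose was also set against the vehicle of its temperature without a test, as a count of genes that differed 2-fold or more.

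The genes named were chosen by a rule fixed before the data were examined. For the treatment comparison these are the 15 largest rises and 10 largest falls past the threshold with the same direction in all 5 treated arrays. For temperature they are the 10 largest each way with the same direction in all 3 pairs, and for the interaction and the slope the 5 largest each way. Where fewer passed, those with the smallest p were added and are said not to pass. Members of 30 gene lists, also fixed before the data were examined, may be named too.

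The lists were tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over the 30 lists. Camera with an estimated correlation and fry were run as alternatives. For single arrays, the median of a list is given with its percentile among 10000 random lists of the same size matched on mean expression. Other settings were no filter, a filter at the 75th percentile, the mean of a gene's probe sets, quantile normalization over the 9 arrays, a prior that allows an intensity trend, other sets of arrays, and each array left out in turn.

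The 3′ minus 5′ log2 difference of the GAPDH and ACTB control probe sets was taken as a sign of RNA integrity or amplification. The code was tested on simulated data with 13504 genes and known changes. Of genes changed by 1 log2 unit it recovered 81% in the treatment comparison, 1% in the interaction and 63% in the temperature comparison. Of genes changed by 2 log2 units it recovered 100%, 55% and 100% in the same order. For the slope the changes were 1 and 2 log2 units per 10-fold dose. The 95% and 100% recovered there are therefore not comparable with the other shares. False calls made up 7.65% of calls in the treatment comparison, 3.45% in the interaction, 6.86% in the temperature comparison and 5.34% in the slope. The simulated errors were independent between genes and arrays, held no batch, and varied alike on vehicle and treated arrays. These shares therefore need not hold for the real arrays. Figures were drawn with matplotlib 3.10.9.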

Results

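Gene expression was measured in cord blood CD34+ cells after 2 h with dmPGE2, a prostaglandin E2 analog that resists breakdown, or with vehicle. The series asks how the response depends on dose and on incubation temperature. At 25 °C there were 4 arrays, with vehicle, 10, 50 and 100 µM dmPGE2. At 37 °C there were 5 arrays, with vehicle, 0.1, 1, 10 and 100 µM. Each combination was measured on 1 array, so no value has replicates of its own, and doses stand in for replicates in the tests. Across probe sets, arrays correlated at r = 0.991 to 0.995 within 25 °C, 0.976 to 0.994 within 37 °C, and 0.944 to 0.963 between temperatures.

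The treatment comparison asked which genes dmPGE2 changed at 10 µM or more, at both temperatures together. MMP9, a matrix-degrading enzyme, rose 4.9-fold (SE 0.15 log2). TAC1, which encodes the substance P precursor, rose 11.9-fold over both temperatures, from 4.2-fold to 4.71-fold at 25 °C and 31.8-fold and 41-fold at 37 °C, over vehicles at 2.94 and 3.35 log2, where signal was low. The kinase genes SGK1 (5.21-fold, SE 0.20 log2) and SIK1 (5.89-fold) rose, as did the chemokine gene CXCL2 (3.59-fold, SE 0.11 log2) and the nuclear receptor gene NR4A3 (3.88-fold). In limma, 39 genes were higher and 7 lower among 13504, and all 46 moved the same way in all 5 treated arrays. Adjusted p was 0.00108 for CXCL2, 0.00112 for MMP9 and 0.0027 for SGK1.

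Other large rises were MCEMP1 (11.2-fold over both temperatures, 4.77-fold to 5.22-fold at 25 °C and 22.5-fold and 34.9-fold at 37 °C), the transcription factor FOXA1 (6.41-fold), carbonic anhydrase CA2 (6.21-fold), BABAM2-AS1 (5.56-fold), the galanin receptor GALR2 (5.05-fold), the vesicular transporter SLC32A1 (4.77-fold), the deiodinase DIO3 (4.12-fold), SYT4 (3.42-fold) and the phosphatase DUSP2 (3.37-fold). Of these 15 rises, TAC1, MCEMP1 and BABAM2-AS1 also differed between temperatures in the interaction (adjusted p = 0.00382, 0.0214 and 0.0158), so their pooled folds average unlike effects. The interaction recovered only 1% of simulated changes of 1 log2 unit. Not passing it therefore does not make the other pooled folds alike at both temperatures. SIK1 rose by 1.44 to 1.72 log2 at 25 °C and by 3.95 and 3.28 log2 at 10 and 100 µM at 37 °C. CA2 rose by 1.4 to 2.13 log2 at 25 °C and by 3.79 and 3.5 log2 at 37 °C. GALR2 rose by 2.73 to 3.01 and by 1.99 and 1.39 log2, and CXCL2 by 1.9 to 1.95 and by 1.73 and 1.76 log2. Standard errors over the 15 largest rises ran from 0.11 to 0.53 log2. TAC1 and FOXA1 were at 2.94 and 4.28 log2 in the 25 °C vehicle, below the lower quartile of that array (5.01 log2). In the 37 °C vehicle they were at 3.35 and 4.01 log2, also below its lower quartile (4.97 log2), so both folds start from low signal. The other bright probe set of SIK1 gave 0.04 log2, and the lowest of NR4A3 1.03 log2. The 7 genes that fell were LOC729732 (2.49-fold), PLPP6 (2.14-fold), ZBTB26 (2.12-fold), C16orf54 (2.1-fold), FOXO6 (1.98-fold), MAP9 (1.75-fold) and ZNF137P (1.75-fold). The other bright probe sets of LOC729732, ZBTB26 and MAP9 gave -0.14, 0.02 and -0.31 log2. HAUS6, PRR15 and TEFM were 1.62-fold, 1.77-fold and 1.82-fold lower but did not pass, at adjusted p = 0.0547, 0.0608 and 0.0619.

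Leaving out any of the 7 arrays moved these counts by more than 1.5 times. Fits that leave out a vehicle, and fits within 1 temperature, keep 1 vehicle array, so their spread comes from the treated arrays only. With the temperature term kept, leaving out the 25 °C vehicle estimates the same effect as the 37 °C arrays alone at 10 and 100 µM. Both had a median of -0.0588 log2 over genes. Leaving out the 37 °C vehicle likewise estimates that of the 25 °C arrays alone (0.0204 log2 in both). Unlike counts within such a pair of fits come from the spread and degrees of freedom used, so 0 calls do not show an absent response. Without the 10, 50 or 100 µM array at 25 °C, 8, 5 and 7 genes were higher and 0 lower. Without the 10 or 100 µM array at 37 °C, 6 and 21 were higher and 0 and 1 lower. Without the 37 °C vehicle 9 were higher and 0 lower, and without the 25 °C vehicle 395 were higher and 323 lower. In fits chosen after the data were seen, the 25 °C arrays alone called 9 genes higher and 0 lower, and the 37 °C arrays alone at 10 and 100 µM called 0 in limma, with 1789 genes at an unadjusted p under 0.05.

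The fixed lists described the treatment response by group. Among 21 tested early targets of cAMP and its transcription factor CREB, all 21 had positive differences, with a median of 0.93 log2. Of these, 4 passed over all genes (SGK1, SIK1, NR4A3 and RGS2, the last at 3.34-fold) and 18 passed when adjusted over the list alone, camera adjusted p = 4.49e-24. Among those that passed only over the list alone, CREM was 6.41-fold and NR4A2 6.13-fold higher. Both also passed in the interaction, so these pooled folds average unlike effects. CREM differed from vehicle by 1.13 to 1.23 log2 at 25 °C and by 4.54 and 4.24 log2 at 10 and 100 µM at 37 °C. NR4A2 differed by 1.2 to 1.67 log2 at 25 °C and by 4.22 and 3.61 log2 at 37 °C. Of 19 immediate early genes, 2 passed, DUSP2 and CCN1 (3.29-fold), and 12 passed when adjusted over the list alone, camera adjusted p = 1.98e-12. FOS, FOSB, JUNB, ATF3 and DUSP1 belong to both lists, so the results of the lists are not separate. Neither list held when the correlation was estimated (adjusted p = 0.326 with an estimated correlation for both), nor did any other list in the 4 comparisons. By fry, adjusted p was 0.0531 for the cAMP list and 0.0418 for the immediate early list.

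In the list of prostaglandin receptors and enzymes, the receptor PTGER4 rose 2.43-fold and the synthase PTGS2 2.28-fold, and 14 of 16 did not pass (camera adjusted p = 0.0631, fry adjusted p = 0.0418). In the homing and adhesion list, the chemokine receptor CXCR4 rose 2.59-fold beside MMP9, and 24 of 26 did not pass (median -0.01 log2, mean 0.20 log2, camera adjusted p = 0.179). The cell cycle inhibitor CDKN1A rose 2.39-fold, the only call among 13 in its list (camera adjusted p = 0.00748). That list shares BTG2, KLF2 and EGR1 with the immediate early genes. CXCL2 and TNFAIP3 (1.72-fold) were the calls among 21 inflammatory and NF-kB targets (camera adjusted p = 0.0132). The median of that list turned between arrays, at 0.36, 0.36 and 0.30 log2 at 25 °C, and at -0.38, -0.25, 0.30 and -0.43 log2 at 0.1, 1, 10 and 100 µM at 37 °C, where 4 members were higher and 5 lower by 2-fold at 100 µM. PFKFB3 (2.02-fold) and VEGFA (1.99-fold) were those among 19 glycolysis and hypoxia genes (camera adjusted p = 0.00214), whose median was -0.02 log2 at 100 µM and 25 °C. The 12 cholesterol synthesis genes held 0 calls in limma (camera adjusted p = 0.0287). For the inhibitor, cholesterol and glycolysis lists adjusted p = 0.326 with an estimated correlation, and for the NF-kB list adjusted p = 0.354 with an estimated correlation. Adjusted over the list alone, 2 prostaglandin, 5 NF-kB and 6 glycolysis and hypoxia genes were higher, 3 homing and 3 inhibitor genes were higher and 1 of each lower, and 1 cholesterol gene was higher and 1 lower. VEGFA was also the call among 17 genes of unfolded protein and amino acid stress (camera adjusted p = 0.128).

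The interaction asked whether the dmPGE2 effect differed between 37 °C and 25 °C. DUSP4, a phosphatase that acts on MAP kinases, differed from vehicle by 6.17 and 5.97 log2 at 10 and 100 µM at 37 °C and by 0.47, 0.52 and 0.54 log2 at 10, 50 and 100 µM at 25 °C. The long non-coding RNA LINC00473 differed by 5.57 and 6.06 log2 at 37 °C and by -0.08, -0.07 and -0.37 log2 at 25 °C. The synaptic vesicle gene SV2C, PIERCE2 and the chemokine gene CXCL6 followed, with interactions of 5.19, 5.03 and 4.21 log2. In the 37 °C vehicle LINC00473, PIERCE2 and CXCL6 were at 4.83, 4.26 and 4.41 log2, below the lower quartile of that array (4.97 log2), as CXCL6 was on the 4 arrays at 25 °C (4.21 to 4.59 log2). In limma, the effect at 37 °C minus that at 25 °C was positive for 87 genes and negative for 12, in a fit that does not measure the error of the vehicle array of each temperature. Adjusted p was 0.000148 for DUSP4 (SE 0.24 log2) and 0.000315 for LINC00473 (SE 0.34 log2), both higher in 2 of 2 arrays at 37 °C. The spread in this fit came from the treated arrays, more of them at 25 °C than at 37 °C. Neighbouring doses differed 2-fold in 12 and 21 genes at 25 °C, and 10 and 100 µM in 145 genes at 37 °C. These SEs and adjusted p-values may therefore be too small for effects at 37 °C. Other bright probe sets gave 3.94 log2 for DUSP4 and 2.70 log2 for SV2C.

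The largest negative interactions were those of SMAD6, MYCN, RGS16, CYTH4 and HES1, at -2.43, -2.40, -2.25, -2.20 and -2.15 log2. SMAD6, an inhibitor of BMP signalling, and the transcription factor MYCN differed from vehicle by 0.05 log2 or less at 25 °C, and at 10 and 100 µM at 37 °C by -2.36 and -2.43 log2 and by -2.41 and -2.40 log2. CYTH4 differed by 0.23, 0.31 and -0.01 log2 at 25 °C and by -2.05 and -2.00 log2 at 37 °C. The 12 genes had medians of 0.04, 0.12 and -0.01 log2 at 10, 50 and 100 µM at 25 °C, and of -1.01, -0.93, -1.71 and -1.84 log2 at 0.1, 1, 10 and 100 µM at 37 °C. HES1, a target of Notch signalling, differed from vehicle by 1.43, 1.56 and 1.01 log2 at 25 °C and by -0.84 and -0.79 log2 at 37 °C. The regulator of G protein signalling RGS16 differed by 0.98, 0.98 and 0.68 log2 at 25 °C and by -1.13 and -1.61 log2 at 37 °C. Bright probe sets of CYTH4 ran from -2.71 to 0.14 log2, and those nearest 0 for SMAD6 and MYCN gave -0.33 and -0.07 log2.

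**Figure D1:**
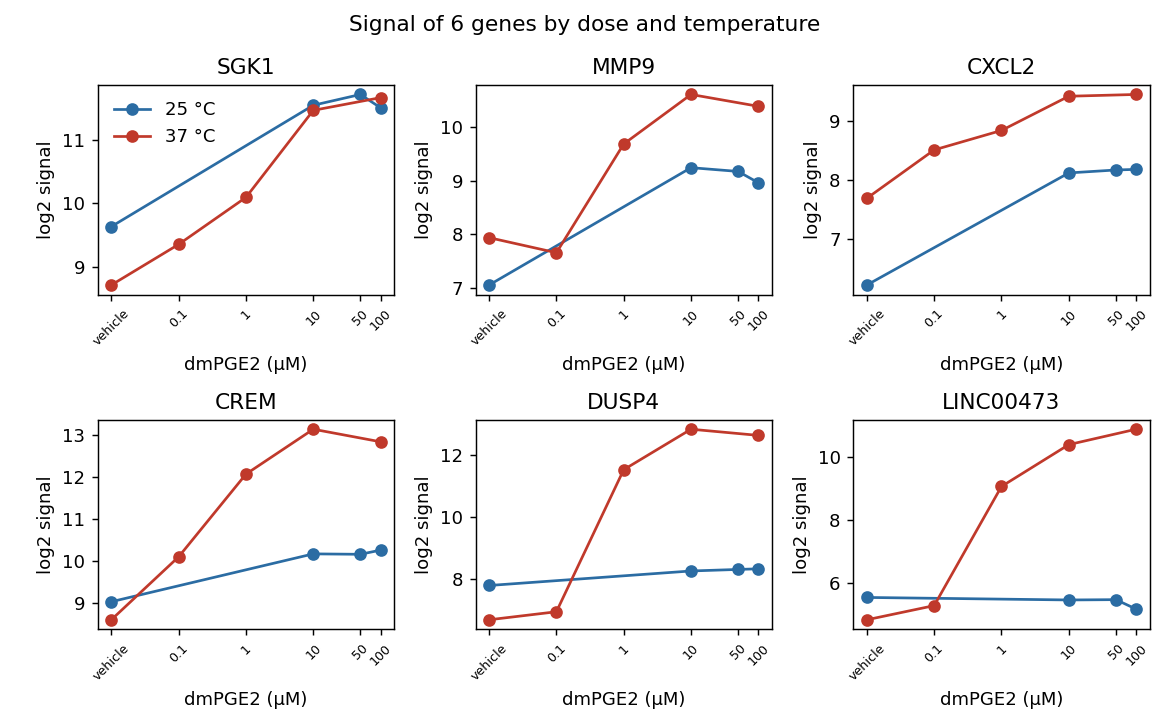
Log2 signal (vertical axes) of 6 genes in vehicle and at each dmPGE2 dose in µM (horizontal axes, doses spaced by log10 with vehicle set apart), with 1 array per point and lines joining the arrays of 25 °C (blue) or 37 °C (red). DUSP4 and LINC00473 lie up to 6.17 and 6.06 log2 above their vehicle at 37 °C and within 0.54 log2 of it at 25 °C, while CXCL2 lies above its vehicle on all 7 treated arrays.

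Of the cAMP and CREB list, 6 of 21 passed in the interaction, CREM, NR4A2, PDE4B, PDE4D, KLF4 and GEM, at 3.23, 2.46, 2.19, 1.92, 1.40 and 3.78 log2 (camera adjusted p = 3.24e-17). Adjusted over the list alone, 13 passed. In the 37 °C vehicle this list had a median 1.15 log2 below that of the 25 °C vehicle. Of 24 cAMP feedback genes, the phosphodiesterases PDE4A (3.41 log2), PDE4B and PDE4D passed (camera adjusted p = 0.00202), and 5 were higher and 1 lower when adjusted over the list alone. FOSL2 (1.60 log2) was the call among 19 immediate early genes, 2 of which passed when adjusted over the list alone (camera adjusted p = 0.018). In limma, 15 interferon targets held 0 calls over all genes or over the list alone (camera adjusted p = 0.0266). For both cAMP lists adjusted p = 0.362 with an estimated correlation, for the immediate early genes adjusted p = 0.624 and for the interferon targets adjusted p = 0.527. By fry, adjusted p was 0.0426 and 0.0297 for the cAMP target and feedback lists.

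Positive interactions in other lists were those of the sphingosine receptor S1PR1 (2.45 log2), the pro-apoptotic gene BCL2L11 (2.96 log2), the glucose transporter SLC2A3 (1.88 log2), CXCL1 (1.80 log2) and CCRL2 (3.01 log2). CXCL1 and CCRL2 belong to the 21 NF-kB targets, whose median was -0.37 log2 (camera adjusted p = 0.394), and S1PR1 to the homing list (camera adjusted p = 0.399). BCL2L11 belongs to the pro-apoptotic list (median -0.21 log2, mean 0.01 log2, camera adjusted p = 0.617) and SLC2A3 to the glycolysis and hypoxia list (camera adjusted p = 0.214). Adjusted over the list alone, 3 NF-kB genes were higher and 5 lower (TNF, NFKBIE, TNFAIP2, ICAM1 and IRF1), 2 pro-apoptotic genes were higher and 1 lower (BMF, -2.35 log2), 2 homing genes were higher and 1 lower (ITGAL, -1.07 log2), and 3 glycolysis and hypoxia genes were higher. Without the 10, 50 or 100 µM array at 25 °C the interaction counts were 23, 21 and 48 higher and 2, 2 and 6 lower. Without the 100 µM array at 37 °C they were 54 and 7, and without the 10 µM array at 37 °C 92 and 37.

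Dose was described array by array, without a test. At 25 °C, 76, 89 and 75 genes differed 2-fold or more from vehicle at 10, 50 and 100 µM, of which 69, 55 and 40 were higher. At 37 °C the totals at 0.1, 1, 10 and 100 µM were 695, 312, 562 and 850, of which 445, 238, 345 and 438 were higher. Between neighbouring doses 12 and 21 genes differed 2-fold at 25 °C, and 396, 238 and 145 at 37 °C. Among the 37 °C arrays the 3′ minus 5′ difference of GAPDH was 1.96 log2 at 100 µM, 1.69 log2 at 0.1 µM and 1.34 log2 in the vehicle, and that of ACTB 3.27, 4.13 and 4.66 log2. The 100 µM array, which also enters the treatment and interaction fits, had the highest GAPDH and the lowest ACTB difference of the 9 arrays. Across probe sets, the 0.1 and 100 µM arrays correlated with the 37 °C vehicle at r = 0.984 and 0.980.

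The 39 genes called higher with treatment had medians of 1.22, 1.20 and 1.18 log2 at 10, 50 and 100 µM at 25 °C. At 37 °C, their medians were 0.43, 1.11, 1.80 and 1.74 log2 at 0.1, 1, 10 and 100 µM. The 0.1 and 1 µM arrays had no part in choosing these genes, but they share the 37 °C vehicle. The 87 interaction genes had medians of 0.15, 0.11 and 0.10 log2 at 25 °C, and 0.31, 1.90, 2.43 and 2.57 log2 at 37 °C. The median of the cAMP and CREB list lay at the 100th percentile of random lists on each of the 7 treated arrays, from 0.49 log2 at 100 µM and 25 °C to 1.64 log2 at 10 µM and 37 °C. These differences share 1 vehicle array per temperature and are not independent, and the list's median was -1.15 log2 for the 37 °C minus the 25 °C vehicle (percentile 0), a difference that enters all 4 values at 37 °C. The random lists were drawn gene by gene and keep no correlation between members. For this list the estimated correlation was 0.5 in the treatment comparison, so its percentiles can overstate how far it stands apart.

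**Figure D2:**
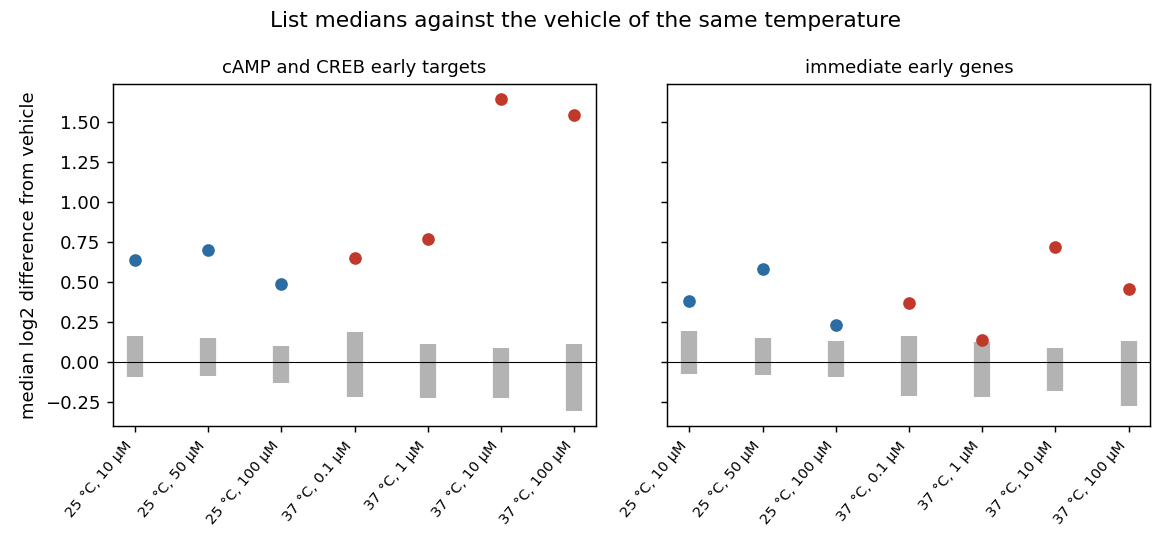
Median log2 difference from the vehicle of the same temperature (vertical axis) for 21 cAMP and CREB early targets and 19 immediate early genes on each treated array (horizontal axis, blue 25 °C, red 37 °C). Grey bars span the central 95% of 10000 random lists matched on expression and drawn gene by gene, without the correlation between members of a real list. The cAMP medians lie above them on all 7 arrays.

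Across 13504 genes, differences from vehicle at 25 °C and 37 °C correlated at r = 0.282 for 10 µM and 0.275 for 100 µM. These correlations use separate vehicles and are across genes, which are not independent replicates.

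The slope on log10 dose among the 7 treated arrays called 0 genes in limma, and 2276 genes had an unadjusted p under 0.05. The smallest adjusted p was 0.0979. LINC-PINT, PLAT, LINC00467, FLJ46875 and THBS1 had the smallest p among positive slopes, at 0.50, 1.00, 0.44, 0.45 and 0.93 log2 per 10-fold dose. PARP8, BBS12, ERCC4, EIF3J-DT and OSGEPL1 had those among negative slopes, at -0.61, -0.45, -0.74, -0.39 and -0.56. Other bright probe sets gave 0.23 for THBS1 and -0.01 for OSGEPL1, and PLAT was at 4.06 to 4.09 log2 in the vehicles, below their lower quartiles. The cAMP and CREB list (0.29 log2, camera adjusted p = 2.96e-12), oxidative stress genes (adjusted p = 0.00341) and immediate early genes (adjusted p = 0.00632) passed as lists, and 15, 2 and 3 of their members passed when adjusted over the list alone. For these 3 lists adjusted p = 0.656 with an estimated correlation. Without the 100 µM array at 37 °C the slope called 98 genes higher and 424 lower, without the 10 µM array at 37 °C 32 and 36, and without the 10 µM array at 25 °C 1 and 0. Without the 0.1 µM array it called 0, and 484 genes had an unadjusted p under 0.05.

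The temperature comparison set 37 °C against 25 °C at matched doses. AHRR, the repressor of the aryl hydrocarbon receptor, was 46.1-fold higher at 37 °C, the serine synthesis enzyme PSAT1 39.8-fold, and the cystine transporter SLC7A11 20.3-fold. The calcium-binding protein gene S100A8 was 16.6-fold lower (SE 0.27 log2), and the transcription factor KLF2 8.27-fold lower. In limma, 2695 genes were higher and 3122 lower, 43.1% of those tested, and 5805 of 5817 kept their direction in all 3 pairs. Of these, 1256 were higher and 1060 lower by 2-fold or more, and temperature cannot be told apart from any batch or cell pool that differed with it. Adjusted p was 0.000357 for AHRR (SE 0.22 log2) and PSAT1 (SE 0.20 log2).

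CXCL5, GCNA, ARFGEF3, IL21R, SAMD4A, CLDN11 and INHBA were 27.0-fold, 21.2-fold, 18.2-fold, 16.7-fold, 16.5-fold, 16.2-fold and 16.0-fold higher. CXCL5 (SE 0.98 log2) differed by 5.34 and 7.43 log2 in the 10 and 100 µM pairs, and was at 5.67 and 7.17 log2 in the vehicles of 25 °C and 37 °C. INHBA differed by 2.03, 4.69 and 5.29 log2 in the vehicle, 10 µM and 100 µM pairs, CLDN11 by 2.91, 4.09 and 5.07 log2, and GCNA by 3.27, 5.07 and 4.87 log2. OSR2, GPR27, RASGEF1B, CTSZ, PROK2, C16orf54, EGR4 and SLA were 16.0-fold, 12.9-fold, 10.8-fold, 10.2-fold, 9.38-fold, 8.02-fold, 7.9-fold and 7.77-fold lower. The bright probe sets nearest 0 gave 0.91 log2 for PSAT1, 1.25 log2 for SLC7A11, 2.05 log2 for IL21R, 0.80 log2 for SAMD4A and 0.01 log2 for CLDN11. For genes lower at 37 °C they gave -0.25 log2 for GPR27, -0.92 log2 for RASGEF1B, -0.11 log2 for CTSZ, -2.65 log2 for KLF2, -0.07 log2 for EGR4 and -1.83 log2 for SLA. ARFGEF3 in the 25 °C vehicle (3.81 log2), and OSR2 and PROK2 in the 37 °C vehicle (4.59 and 4.45 log2), were below the lower quartile of their array.

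Inflammatory and NF-kB genes were higher as a group, 13 of 21 higher and 3 lower (camera adjusted p = 0.00535), with CCRL2 at 15.9-fold, NFKB1 at 5.65-fold and CCL20 at 5.32-fold. The comparison averages the vehicle pair with the 10 and 100 µM pairs, and 58 genes were called both here and in the interaction. CCRL2 is 1 of them, so its fold includes a dmPGE2 effect that was larger at 37 °C. Between the vehicles alone the list median was 0.94 log2 higher at 37 °C. The inhibitor gene NFKBIA was 1.54-fold lower. Of 17 genes of unfolded protein and amino acid stress, 11 were higher and 2 lower (camera adjusted p = 0.00417), with VEGFA at 6.83-fold and CHAC1 at 5.49-fold higher and DDIT3 2.82-fold lower. Of 19 immediate early genes, 14 were lower and 0 higher (camera adjusted p = 0.000701), with FOS at 5.11-fold and EGR1 at 4.83-fold. Of 22 cell cycle genes, 14 were lower and 2 higher (camera adjusted p = 0.00417). RRM2 was 4.26-fold and CCNA2 2.77-fold lower, while CCNB1 was 2.06-fold higher. Of 12 monocyte and neutrophil markers, 10 were lower (camera adjusted p = 0.000701), from 16.6-fold for S100A8 to 1.37-fold for CSF3R. For each of these 5 lists adjusted p = 0.519 with an estimated correlation. Adjusted over the list alone, the counts were the same except that 4 NF-kB genes were lower. The ACTB 3′ minus 5′ difference was 5.06 to 5.25 log2 on the 25 °C arrays and 3.27 to 4.66 log2 on the 37 °C arrays, so this sign of RNA quality differed between the same arrays as the 5 lists.

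**Figure D3:**
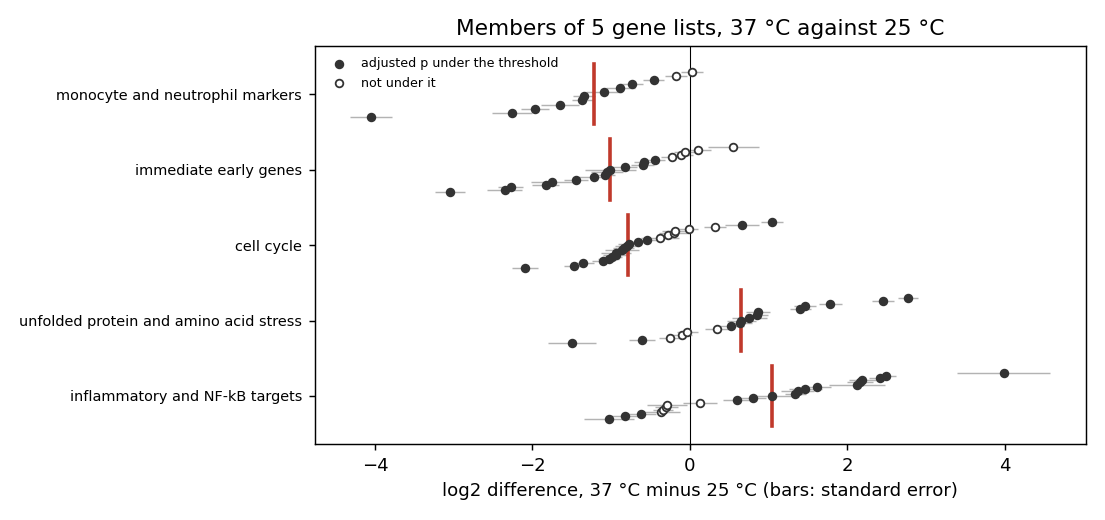
Log2 difference of 37 °C minus 25 °C (horizontal axis) for each tested member of 5 gene lists, with standard errors from limma as grey bars and list medians as red lines. Filled points had an adjusted p under 0.05, which holds for 10 of 12 monocyte and neutrophil markers and 14 of 19 immediate early genes, all lower.

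The prostaglandin receptor gene PTGER2 was 5.78-fold and PTGER4 2.34-fold lower at 37 °C, and HPGDS 6.76-fold lower, with 5 lower and 1 higher of 16 in their list (camera adjusted p = 0.198). Heat shock genes went both ways, 4 of 15 higher and 4 lower (camera adjusted p = 0.583), with HSPA6 at 5.37-fold higher and HSP90AB1 at 3.9-fold lower. Of 5 genes in the cold inducible list, UCP2 was 1.95-fold lower and 4 did not pass (camera adjusted p = 0.796). Of 21 stem and progenitor regulators, 10 were lower and 4 higher (camera adjusted p = 0.131), with MYB at 2.99-fold lower and KIT at 2.01-fold higher. Adjusted over the list alone, 12 of these regulators were lower and 4 higher, and the counts of the prostaglandin, heat shock and cold lists were the same.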

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

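The tests of an atypical vehicle array at 37 °C, of the vehicle difference in the cAMP list and of the 0.1 µM array, with its reference shares, were chosen only after the results were seen, and the GAPDH covariate for temperature was added after the data were seen.

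The interaction stood out because genes passed a direct test of whether the effect of dmPGE2 differed between temperatures. That test holds 1 vehicle array per temperature and does not measure its error. It takes its spread from more treated arrays at 25 °C than at 37 °C. The effect at 37 °C minus that at 25 °C was positive for 87 genes and negative for 12, led by LINC00473, DUSP4, SV2C, PIERCE2 and CXCL6 (5.99, 5.56, 5.19, 5.03 and 4.21 log2) and by SMAD6, MYCN, RGS16, CYTH4 and HES1 (-2.43, -2.40, -2.25, -2.20 and -2.15 log2). The lists that passed had medians of 0.94 (cAMP and CREB early targets), 0.33 (immediate early genes), 0.15 (cAMP signalling feedback) and 0.24 log2 (interferon targets). With an estimated correlation none passed, at adjusted p = 0.362, 0.624, 0.362 and 0.527 in that order.

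Taking any 1 array of each temperature as the vehicle gives 12 choices, too few for a share under 0.05; 3 called at least as many as the real 99 genes, and the highest of the others, which keeps the 37 °C vehicle, called 179, while the 8 choices with another array as the 37 °C vehicle called 0. An atypical 37 °C vehicle alone would leave the 87 genes level between arrays outside the fit, yet 1 µM exceeded 0.1 µM by a median of 1.32 log2 (quartiles 0.78 and 2.24), in 84 of 87 genes. For the 12 genes with a negative interaction the same median was 0.03 log2, and 10 µM minus 1 µM gave -0.773 log2 (quartiles -0.95 and -0.48) but 0.04 log2 in the 37 genes called without the 10 µM array at 37 °C, so selection could give that fall, and a fall with dmPGE2 and a high 37 °C vehicle cannot be told apart, except that the differences of HES1 and RGS16 at 25 °C do not involve that vehicle. The difference between vehicles made up 3.61% of the median interaction of the 87 genes (bootstrap interval over genes -3.2% to 20.5%). That argues against it as the whole source in these arrays, though the 87 genes were chosen by this same interaction. For the cAMP and CREB list it equals 123% (interval over genes 34.5% to 299%), with treated arrays at a median of -0.42 log2 for 37 °C minus 25 °C. For that list a larger response and a lower starting level at 37 °C cannot be told apart with 1 vehicle array per temperature. Both intervals treat genes as independent and leave out the error of the vehicle arrays. A cell pool or batch that differed between temperatures stays open, as does an untested effect of temperature on the response.

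The 43.1% of genes that differed between temperatures came from 3 arrays against 3, which make 10 splits, too few for a share under 0.05. The real split called 5817 genes, 1 split reached that, and the highest of the others called 0. With the GAPDH 3′ minus 5′ difference as a covariate, 90.3% of the calls were still called. That difference did not separate the temperatures. It was 1.34 and 1.46 log2 in the 37 °C and 25 °C vehicles and 1.31 and 1.26 log2 at 10 µM. At 100 µM it was 1.96 and 1.57 log2. A covariate that does not separate the groups can take away few of their calls, so this fit does not decide on RNA quality. The ACTB difference separates the temperatures, was not used as a covariate and stays open, as do cell pool and batch.

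At 0.1 µM and 37 °C, 695 genes differed 2-fold from vehicle. Of these, 19.4% also did so in the same direction at 1 µM (exact binomial interval over genes, as if independent, 16.5% to 22.6%). With a shared vehicle, 92.8% had the same sign there. Selection at the lower dose lowers such a share, but between 1 and 10 µM it was 64.1% and between 10 and 100 µM 69.4%. Noise in the 0.1 µM array would lower the share even where the response to dose only climbs. The share therefore does not decide on the shape of the dose response. The 39 genes called higher with treatment had medians of 0.43, 1.11, 1.80 and 1.74 log2 at 0.1, 1, 10 and 100 µM at 37 °C. Across genes, the difference of 0.1 µM from vehicle correlated with that of 100 µM from 10 µM at 37 °C, which shares no array with it. The value was r = 0.598 (bootstrap interval over genes, as if independent, 0.583 to 0.611), and 100 µM minus 10 µM at 25 °C gave r = -0.04. RNA degradation or amplification shared by several arrays is a candidate explanation, since GAPDH 3′ minus 5′ was higher at 0.1 µM than in vehicle (1.69 and 1.34 log2), and at 100 µM than at 10 µM (1.96 and 1.31 log2), but ACTB was lower in both (4.13 and 4.66, 3.27 and 4.30 log2); that both signs must rise was required only after r was seen, and it cannot be told apart from another structure among the arrays.

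The treatment comparison called 46 genes, and 2 of the 21 splits of its 7 arrays into 5 and 2 called as many, so this count does not exclude chance. The highest of the others called 770 genes; it took the 10 and 100 µM arrays at 37 °C as the pair, which with the temperature term sets them against the 37 °C vehicle, so the structure it follows is the treated arrays at 37 °C. The other 19 splits called 0.

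Probe sets with no gene name here were not part of the comparisons. Among 4691 of them above the filter, 43 were called for treatment and 36 for the interaction, a signal outside the genes compared here.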

How the results depend on the processing

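The fits within 1 temperature and those with the GAPDH difference in the interaction and temperature comparisons were chosen after the data were seen; the others were fixed before. No paired analysis was possible because replicate numbers, with 1 array per dose and temperature, pair no arrays; the temperature comparison matches arrays by dose only. For the named genes and lists no estimate changed sign under any alternative run. Of their values, 762 stayed on their side of the threshold, 270 fell short of it and 22 came to pass it. Some settings are the same fit, such as matched doses only and leaving out the 50 µM array at 25 °C. These values are therefore not all separate checks. Most losses, 226, were named genes of the treatment comparison. Named treatment genes were chosen for the same direction in all 5 treated arrays, and named temperature genes for that in all 3 pairs. This choice largely fixes their sign in fits that leave out arrays, so their signs there are no test. Among the 762 values, 119 were of named slope genes, which did not pass in the main fit either.

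Treatment (39 higher, 7 lower) had 13 lower with the mean of probe sets and 14 with the intensity trend. With all 9 arrays and any dose as treated, or without the temperature term, 0 were higher and 0 lower in limma (989 and 337 at an unadjusted p under 0.05). With matched doses only, 5 were higher and 0 lower, with the 25 °C arrays only 9 and 0, and with the 37 °C arrays only 0 and 0, at 10 and 100 µM and at all 4 doses (1789 and 1097 unadjusted). Leaving out each array gave 5 to 395 higher and 0 to 323 lower. The interaction (87 and 12) had 21 higher and 2 lower with matched doses only, and 21 to 92 higher and 2 to 37 lower on leaving out arrays; a vehicle left out gives no estimate. The slope (0 and 0) gave 0 to 98 higher and 0 to 424 lower. Fewer arrays leave fewer degrees of freedom. The treatment fit without the 25 °C vehicle and that of the 37 °C arrays at 10 and 100 µM estimate the same effect. Their counts differ through the spread and degrees of freedom used. The cause was otherwise not tested. Temperature counts stayed within 1.5 times in each alternative run, with 1992 to 2313 higher and 2094 to 2701 lower on leaving out arrays. Leaving out either array of a dose pair gives the same temperature fit, so these runs hold 1 distinct fit per pair. A 1.5-fold threshold, looser by construction, counted 566, 522 and 682 genes at 25 °C (10, 50, 100 µM) and 2530, 1440, 1931 and 2711 at 37 °C (0.1, 1, 10, 100 µM). With the 2 vehicle arrays alone, 2356 genes differed 2-fold between temperatures.

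Lists passing were 6 for treatment, 4 for the interaction, 3 for the slope, all higher by camera, and 2 higher and 3 lower for temperature. When the correlation was estimated, 0 passed in each comparison. By fry, 2 lists passed higher for treatment, 2 for the interaction and 0 for the slope, and for temperature 4 were higher and 11 lower. Lists lower at 37 °C numbered 7 with the mean of probe sets and 5 with no filter; the cause was not tested.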

Other observations

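In the temperature comparison, markers of several blood lineages were called, as were 43.1% of all genes tested. Counts near that share do not set a list apart, and no list named in this paragraph passed in camera. By fry, which does not compare a list with other genes, adjusted p was 0.0142 for basophil and mast cell markers. It was 0.0206 for natural killer cell, 0.0371 for T cell, 0.00947 for B cell and 0.0247 for erythroid markers. Of 9 B cell markers, 3 were lower and 0 higher (camera adjusted p = 0.315). Of 9 erythroid markers, 2 were lower and 1 higher (camera adjusted p = 0.385). Of 8 basophil and mast cell markers, 4 were lower and 0 higher, with the immunoglobulin E receptor gene FCER1A at 4.67-fold and CPA3 at 2.28-fold lower (camera adjusted p = 0.0791). Of 7 natural killer cell markers, 4 were lower, with GZMA at 4.26-fold (camera adjusted p = 0.115). Of 10 T cell markers, 3 were higher, among them CCR7 (5.75-fold) and CD8A (3.05-fold), 0 were lower and 7 did not pass (median 0.21 log2, camera adjusted p = 0.379). Of 12 clock genes, 3 were higher, CRY1 (3.25-fold), CRY2 (2.14-fold) and BHLHE40 (1.77-fold), and 2 lower, NFIL3 (1.84-fold) and NR1D2 (1.44-fold) (median -0.01 log2, mean 0.18 log2, camera adjusted p = 0.547 for the list).

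No test in this part was chosen after its own result was seen; the tests that follow were written before their results were seen, on lists drawn up after AHRR, PSAT1 and SLC7A11 had led the temperature comparison; of their members, NQO1 had been seen. The hypothesis that targets of the amino acid response factor ATF4 are higher at 37 °C was tested on 21 further targets. Of these 14 were higher, with a median of 0.89 log2 over the list, and PSPH was lower. Limma's camera gave p = 9.92e-08 at the preset correlation and p = 0.106 with an estimated correlation, so the list's shift against other genes rests on the preset correlation. The largest were SLC7A5 (4.54-fold), SLC3A2 (4.35-fold), AARS1 (3.63-fold) and SLC7A1 (3.44-fold). An effect of temperature and a batch or cell pool that differed between temperatures cannot be told apart here.

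The hypothesis that aryl hydrocarbon receptor targets are higher at 37 °C stayed undecided. Of 5 tested targets other than AHRR, 2 were called higher, CYP1A1 (3.03-fold) and CYP1B1 (2.32-fold), and CYP1A2, TIPARP and NQO1 did not pass. CYP1A1 was at 8.67 log2 in the 0.1 µM array, below the 10.07 to 10.48 log2 of the other arrays at 37 °C.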
